A study of Mus musculus with 12 samples.

How the data were processed

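Total RNA of whole urinary bladder was measured in 12 samples from female C57BL/6 mice, 10 weeks old, on Agilent 1-colour (Cy3) mouse expression arrays. The mice were kept for 2 weeks under 12 h of light and 12 h of dark and then in constant darkness. They were killed at circadian time (CT) 0, 4, 8, 12, 16 or 20 h, with 2 arrays per time. The labels do not state how long the mice had been in darkness, nor that each array held 1 mouse, so p-values here measure the spread between arrays. The series' design text leaves CT16 out of its list of times, and the labels of 2 arrays give that time.

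The deposited scanner files hold intensity per spot as made by Agilent Feature Extraction 10.5.1.1, detrended within each array and not normalised between arrays. The deposited files' other columns hold yes-or-no marks per spot, such as well above background or outlier. A value table by the authors holds log2 values for 27883 of 41174 probes. Its 12 columns have nearly the same distribution, with a mean absolute difference of 0.00500 between each column's sorted values and their mean, as quantile normalisation leaves them. The submitters' notes name R 2.8.1 and do not state the normalisation or filter behind that table, so it was used as an alternative only.

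Log2 processed signals of 43379 non-control spots were averaged per probe. They were then scaled by subtracting the array's 75th percentile over these probe means. A level of 0 thus equals that percentile. Spots marked as outliers were dropped before the averaging. After it, 271 probes without a value on some array were left out. Names came from the RefSeq accession in the files for 22951 probes, from a current symbol for 6659 and from a synonym for 3109. Another 8455 probes kept the name in the files. The name table was that of GRCm38.p6 and gave names only. Probe coordinates are those of the array files, on mm7, and no annotation of that build was at hand to place a probe in an exon or UTR. Each name was represented by its probe of highest mean level, and 18394 names well above background on at least 4 of the 12 arrays were tested; they are called genes here, although 3766 of them carry an accession, a clone name or another placeholder.

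Harmonic regression with cosine and sine terms of a 24 h period was fitted in limma 3.58.1 under R 4.3.3, with a moderated F-test on 9 residual degrees of freedom before the variance prior. Amplitude and peak time carry delta-method standard errors (SE). The fold of a wave is its fitted peak over its fitted trough, and its range is the fold at the amplitude minus and plus 1 SE. A 1-way fit over the 6 times, with 6 residual degrees of freedom, gave an F-test for any difference and the contrasts CT12 minus CT0, CT16 minus CT4 and CT20 minus CT8. A further fit tested 12 h terms beyond the 24 h terms. All p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All tests were two-sided or F-tests unless stated.

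The tests and 25 gene lists were fixed before the data were examined. Each list's members were counted over all genes and adjusted over the list alone. Its mean profile, with each member centred and divided by its SD, was tested for a 24 h wave by an exact permutation test over 1247400 assignments of the 12 arrays to times (Python 3.11.15, numpy 2.4.6). Hepatocyte, slow and cardiac muscle, and autonomic ganglion neuron lists were added after the main components of the data had been seen. The rule for named genes took every measured core clock gene and connexin and, among 24 h genes well above background on all arrays and with a gene name, the 10 largest amplitudes with a peak from CT0 to CT12 and the 10 from CT12 to CT24. It also took up to 3 24 h genes of each other list, and for each contrast the 3 highest and 3 lowest changes past the threshold without overlap between the arrays compared. Not every gene the rule took is printed, and genes outside it are said to be so.

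The files place CT0 and CT4 on slide 1, CT8 and CT12 on slide 2, and CT16 and CT20 on slide 3, all scanned on 1 day. A fit with slide as a fixed block uses differences within slides alone; a fit with slide as a random block was added later. Alternatives covered background correction (normexp, offset 50), quantile and median scaling, the authors' table, the filter on dim probes, the choice of probes, replicate number as a block, array weights, an intensity trend in the variance prior, an F-test without the prior, and leaving out each array. Between 64.2% and 70.2% of spots were well above background on each array, and no spot was saturated. The number of arrays limits the precision. On simulated data with 200 waves among 18394 genes, the 24 h fit recovered 20.9% of waves of amplitude 0.3 (log2), 74.6% of amplitude 0.6 and 86.4% of amplitude 1. With the slide block the same shares were 0%, 17.9% and 51.5%.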

Results

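Gene expression over 1 circadian day was measured in the urinary bladder of female C57BL/6 mice held in constant darkness, where rhythms run without a light signal. The samples were 2 arrays at each of CT0, CT4, CT8, CT12, CT16 and CT20; CT0 to CT12 is the subjective day, the rest phase of mice, and CT12 to CT24 the subjective night. The study behind the series asked whether the bladder has a clock of its own and whether connexin 43, a gap junction protein that couples bladder muscle cells, follows it. The 75th percentile of signal over spots was 844 to 984 intensity units per array. Across genes, levels of the 2 arrays of a time correlated at r = 0.984 to 0.993; genes are not independent replicates. The SD of the log2 difference between the 2 arrays of a time was 0.391 to 0.589.

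Core clock genes ran in opposite phases over 24 h. Arntl, which encodes the clock activator BMAL1 (probe on chromosome 7, 109229489 to 109229548, mm7), peaked at CT22.5 ± 0.35 h (SE) with a peak 9.02-fold above its trough (amplitude 1.59 ± 0.14, log2, 12 arrays, adjusted p = 0.00204). Nr1d1, encoding the repressor REV-ERB alpha (chromosome 11, 98878251 to 98878753, mm7), peaked at CT6.8 ± 0.17 h with an 11.5-fold wave (range 10.4 to 12.8 for 1 SE, adjusted p = 9.8e-06). Nr1d2, its paralog, peaked at CT10.3 (3.44-fold, adjusted p = 0.000306) and the repressor gene Per2 at CT12.7 ± 0.31 h (5.03-fold, range 4.41 to 5.73, adjusted p = 0.000892). Of the 18 measured members of the core clock list, 9 passed over all genes and 13 adjusted over the list alone. The 9 became 4 to 8 with 1 array left out, 5 with no filter on dim probes, 4 with slide as a random block, 1 with slide as a fixed block and 4 without the 3 arrays highest in hepatocyte or in slow muscle transcripts.

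Members past the threshold over all genes also included Per1 (4.76-fold, CT10.7), Per3 (4.43-fold, CT11.7), Npas2 (3.21-fold, CT23.1) and Cry2 (1.65-fold, CT10.9). Cry1 had a 2.32-fold fitted wave at CT17.1 and missed it (adjusted p = 0.0651); it passed in 7 of 15 other settings and in none of the 12 fits that left out an array, and a second Cry1 probe had a 2.17-fold wave at CT17.4 (unadjusted p = 2.1e-06). Further probes of other members gave smaller or less certain waves: 1.41-fold for Per2 (unadjusted p = 0.0544), 1.62-fold for the weakest of 3 Nr1d1 probes (0.0438) and 2.79-fold for Cry2 (0.0508). Clock missed it too (1.46-fold, CT23.3, adjusted p = 0.0952), with 1.57-fold (unadjusted p = 0.000837), 1.88-fold (0.00540) and 1.37-fold (0.220) waves on its other probes. Csnk1d (1.20-fold) and Fbxl21 (1.35-fold) passed over the list alone; the other Csnk1d probes had 1.06-fold to 1.15-fold waves (unadjusted p = 0.246 to 0.630). Rora, Csnk1e, Btrc and Timeless passed neither, with fitted folds of 1.15 to 1.31 on the probes used. Other Rora probes had larger waves, 1.55-fold at CT8.4 (unadjusted p = 0.0210) and 1.33-fold (0.0514), and another Timeless probe 1.25-fold (0.671). Because members peak in opposite phases, the list's mean profile had a small amplitude of 0.22 SD units (exact permutation p = 0.0438, adjusted p = 0.301). Per1 and Per3 stayed past the threshold in 1 of 12 fits that left out an array, Npas2 in 3 and Cry2 in 4. Arntl, Nr1d1, Nr1d2 and Per2 stayed past it in all 12. The mean level of Per1 was highest at CT12 (2.06, against 0.91 at CT8 and 0.21 at CT16), later than its fitted peak. In the 1-way test for any difference between times Per1 passed (limma adjusted p = 0.00990). Per3 (0.118), Npas2 (0.159) and Cry2 (0.0943) did not pass that test.

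**Figure D1:**
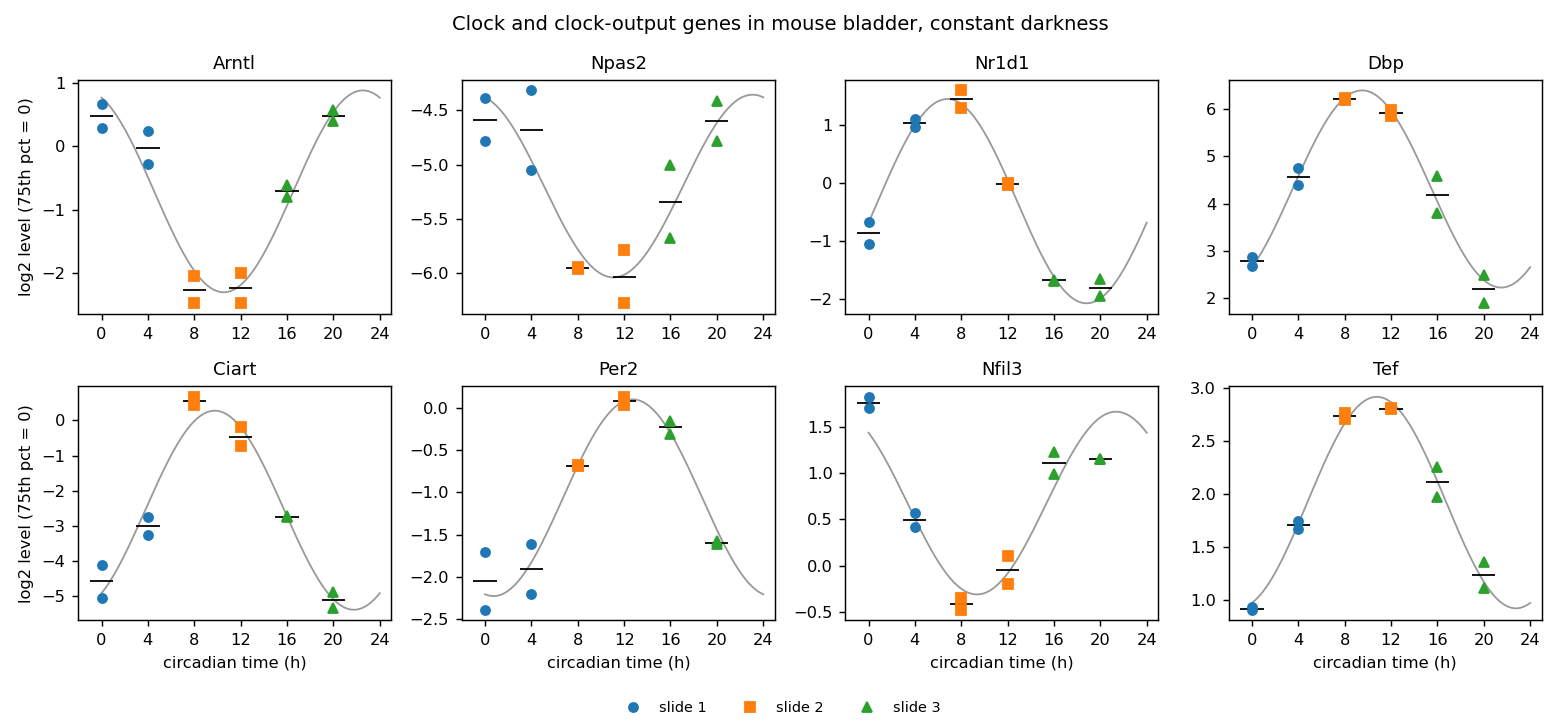
Log2 level (75th percentile of the array = 0) against circadian time in hours for Arntl, Npas2, Nr1d1, Dbp, Ciart, Per2, Nfil3 and Tef. Points are single arrays, coloured and shaped by slide, bars are the means of 2 arrays and grey curves the fitted 24 h waves; Arntl, Npas2 and Nfil3 are highest between CT20 and CT0 and lowest between CT8 and CT12, when Dbp, Ciart and Tef are highest.

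Ciart and Dbp, outputs of the clock, had the largest waves of all 24 h genes. Ciart, which encodes a repressor of BMAL1 (named Gm129 in the files, chromosome 3, 95752460 to 95752519, mm7), peaked at CT9.8 ± 0.27 h with a 50.2-fold wave (range 38.0 to 66.3, adjusted p = 0.000306). Dbp, a transcription factor gene that BMAL1 activates (chromosome 7, 41886169 to 41886228, mm7), had an 18.1-fold wave at CT9.5 ± 0.20 h (amplitude 2.09 ± 0.11, log2, adjusted p = 2.3e-05). Its relatives Tef (4.00-fold, CT10.8) and Hlf (3.96-fold, CT12.3) peaked near it, and Nfil3, whose protein represses through the same DNA sites, peaked at CT21.4 ± 0.47 h (3.92-fold, adjusted p = 0.0130). The deubiquitinase gene Usp2 had a 7.02-fold wave at CT11.4 (adjusted p = 0.00251). Of the 17 measured members of the clock output list, 10 passed over all genes and 15 adjusted over the list alone, with 8 to 10 over all genes when 1 array was left out, 4 without the 3 arrays highest in hepatocyte or in slow muscle transcripts and none with slide as a fixed block. The mean profile peaked at CT12.4 (exact permutation p = 0.00053, adjusted over 25 lists 0.0131). With slide means removed and arrays reassigned within slides, the exact p was 0.0278 (adjusted p = 0.116). Within slides this list did not stand out: the autonomic receptor, cell cycle and sterol synthesis lists reached the smallest p of that test, 0.00926 (adjusted p = 0.0772), and the fibroblast and immediate early lists also had 0.0278.

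Across the genome, 114 of 18394 genes (0.620%) had a 24 h wave past the threshold, and 2892 had an unadjusted p under 0.05. Spon2, encoding an extracellular matrix protein, had a 7.04-fold wave at CT0.8 ± 0.37 h (range 5.83 to 8.51, adjusted p = 0.00251). The hyaluronan synthase gene Has2 peaked at CT2.1 (3.49-fold; 2.17-fold with unadjusted p = 0.0683 on a second probe) and Adamts4, a protease of matrix proteoglycans, at CT23.1 (4.65-fold, adjusted p = 0.0107). Cys1, encoding the ciliary protein cystin, peaked at CT14.8 ± 0.26 h (4.64-fold, adjusted p = 0.000306). Further large waves were those of Angptl7 (6.22-fold, CT16.8), Plk5 (5.95-fold, CT14.0), Tsc22d3 (3.51-fold, CT13.2) and the carbonic anhydrase gene Car14 (3.51-fold, CT12.2). These were less stable: Angptl7 passed in 5 of 12 fits that left out an array, Plk5 in 3, Tsc22d3 in 6 and Car14 in 2. None of them passed with slide as a random block (limma adjusted p = 0.0523 to 0.151). Adamts4 and Nfil3 also missed the threshold there (limma adjusted p = 0.0523 for each). Tcap, encoding a protein of the striated muscle sarcomere, had a 12.0-fold wave at CT9.8 (8.07 to 17.9, adjusted p = 0.0458); its 2 arrays at CT0 differed widely (SD 1.38, log2), and it passed in 2 of 12 fits that left out an array.

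The median 24 h gene had a 1.98-fold wave; 109 reached 1.5-fold, 55 reached 2-fold and 15 reached 4-fold. Peaks fell in the subjective day for 74 genes and in the subjective night for 40 (35.1%, exact binomial 95% interval 26.4% to 44.6%, counting error only, with genes not independent). With median scaling the share was 51.6%. Most often, in 37 genes, the peak lay between CT4 and CT8, and least often, in 6, between CT16 and CT20. The 24 h gene Npy2r, outside the naming rule, was below background at some times.

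Time and slide are partly confounded, since each slide held 2 neighbouring times. With slide as a fixed block, limma left 2 genes past the 24 h threshold, Nr1d1 (15.1-fold, adjusted p = 0.0123) and Rasgrf1, a gene outside the naming rule that did not pass without the block (1.61-fold, adjusted p = 0.263); 2532 genes had an unadjusted p under 0.05. Within slides, 97 of the 114 genes had an unadjusted p under 0.05 and 112 a peak within 3 h of the one above, and their median fold was 2.05. These genes were chosen by a fit that includes the differences within slides, so the selection itself favours this agreement. Asic2 and Npas2 were the named 24 h genes that missed an unadjusted 0.05 within slides, among 27 examined. With slide as a random block (estimated correlation 0.143) 28 genes passed, Arntl (adjusted p = 0.0109), Ciart (0.00206), Dbp (0.000129) and Per2 (0.00446) among them. With the mean profile of the hepatocyte list as a covariate over all 12 arrays 86 genes passed, 74 of them among the 114. Without CT4 replicate 1 the count was 53, without CT4 replicate 2 52, without CT8 replicate 1 63, without CT8 replicate 2 69, without CT12 replicate 2 43, without CT16 replicate 1 42, without CT16 replicate 2 48, without CT20 replicate 1 59 and without CT20 replicate 2 62. Without the 3 arrays highest in hepatocyte transcripts it was 18, and without the 3 highest in slow muscle transcripts 18, with 9 arrays left in each.

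**Figure D2:**
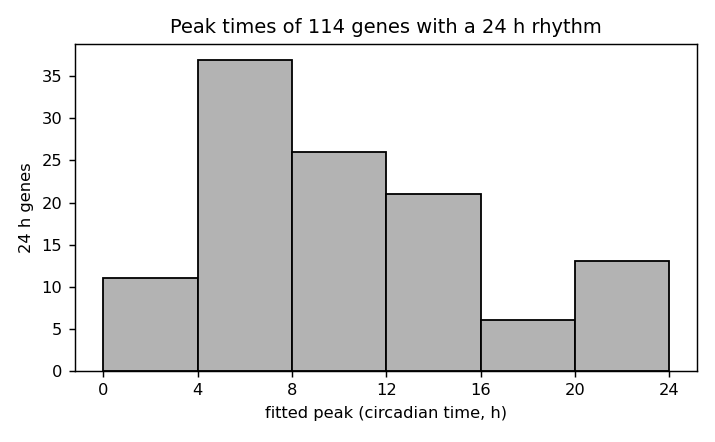
Number of genes with a 24 h rhythm (vertical axis) by fitted peak time in circadian hours, in bins of 4 h. The bins hold 11, 37, 26, 21, 6 and 13 of the 114 genes.

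Gja1, encoding connexin 43 (chromosome 10, 56207239 to 56207298, mm7), had a fitted peak at CT10.9 ± 0.74 h, 2.02-fold above its trough (range 1.76 to 2.31). Its mean log2 level was -0.76 ± 0.28 (SD, n = 2) at CT8 and -0.77 ± 0.12 at CT16, against -1.44 ± 0.16 at CT0 and -1.78 ± 0.20 at CT20. This wave missed the threshold over all genes (limma adjusted p = 0.0846) and passed adjusted over the list alone (p = 0.0145); a permutation of its own 12 values gave an exact p of 0.00527. None of the 12 fits that left out an array and none of 15 other settings took Gja1 past the threshold over all genes. With the slide block its fold was 2.75 at CT11.6 over the 12 arrays (limma, adjusted p = 0.276).

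No member of the connexin list passed over all genes, and 2 of 13 passed adjusted over the list alone. The second was Gjc3, a connexin gene of glia, with a 2.11-fold fitted wave at CT6.4 and a low level (adjusted p = 0.153 over all genes, 0.0436 over the list). Gjc1, the smooth muscle connexin 45 gene, had a fitted fold of 1.24 (1.13 to 1.36, adjusted p = 0.400). The epithelial connexin genes Gjb2 (1.22-fold), Gjb5 (1.73-fold) and Gjb6 (1.31-fold), the vascular Gja4 (1.14-fold) and Gja5 (1.12-fold), and Gjb1, Gjd3 and Tjp1 (1.04-fold to 1.40-fold) passed neither. Other probes of Gjb2, Gjb6, Gja5, Gjc1 and Tjp1 had 1.08-fold to 1.42-fold waves (unadjusted p = 0.0796 to 0.742). The list's mean profile had no wave past the threshold (exact permutation p = 0.783, adjusted p = 0.889).

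**Figure D3:**
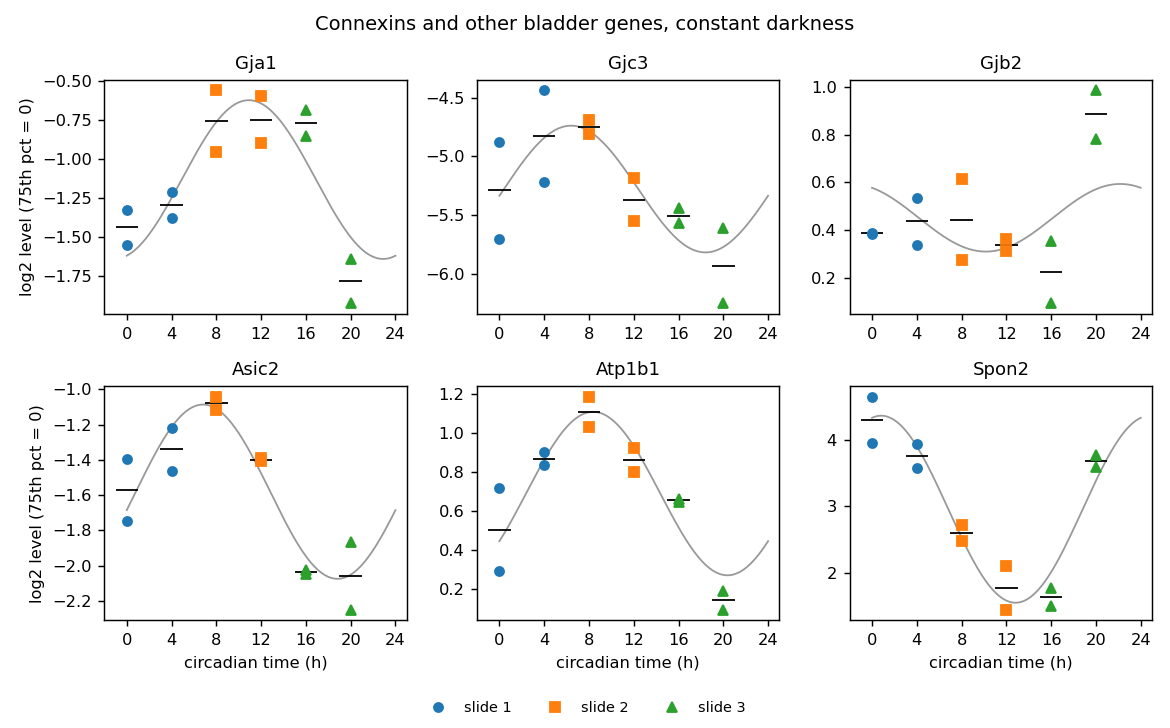
Log2 level (75th percentile of the array = 0) against circadian time in hours for the connexin genes Gja1, Gjc3 and Gjb2 and for Asic2, Atp1b1 and Spon2. Points are single arrays by slide, bars means of 2 arrays and curves fitted 24 h waves; Gja1 is lowest at CT20, with a mean of -1.78.

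Among the bladder's sensing and transport genes, Asic2, an acid-sensing ion channel gene (Accn1 in the files), peaked at CT6.8 ± 0.52 h (1.98-fold, range 1.81 to 2.18, adjusted p = 0.0239). Atp1b1, encoding a subunit of the sodium pump, peaked at CT8.4 ± 0.56 h (1.79-fold, 1.64 to 1.95, adjusted p = 0.0332). Asic2 was the 1 of 20 measured stretch and purinergic genes to pass, over all genes and adjusted over the list alone. Of 22 water and ion transport genes, 1 passed over all genes and 2 over the list alone, the other being Clca1 (1.63-fold, adjusted p = 0.0954 over all genes). Asic2 stayed past the threshold in 5 of 12 fits that left out an array and Atp1b1 in 3. The mean profiles of these lists had adjusted exact p-values of 0.733 and 0.773.

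Klf9 (2.09-fold, CT10.8), Per1 and Tsc22d3 were the 3 of 19 measured glucocorticoid-responsive genes past the threshold over all genes; adjusted over the list alone 10 passed, among them Fkbp5 (2.48-fold, CT12.3) and the metallothionein gene Mt2 (1.78-fold, CT5.7). The list's mean profile had an exact p of 0.0239 (adjusted p = 0.299). In the Rev-erb and Sp1 list 3 of 13 passed over all genes, Nr1d1 and Nr1d2 among them, and 4 over the list alone, including Tbl1x (1.28-fold); Sp1 was in neither count, and the mean profile had an adjusted p of 0.607. Cirbp (1.78-fold, CT7.9) and Rbm3 (1.52-fold, CT10.8), genes of cold-inducible RNA-binding proteins, were 2 of 3 past the threshold over their list alone and 0 over all genes (profile adjusted p = 0.301). Other lists had no member past the threshold over all genes. Over the list alone 4 of 24 oxidative stress genes passed (profile adjusted p = 0.889), among them Cyp1a1 (3.80-fold, CT13.3), and 1 each passed of 19 endoplasmic reticulum folding genes (Pdia4, 1.55-fold; profile 0.301), 19 smooth muscle contractile genes (Smtnl2, 1.78-fold; profile 0.889), 25 cell cycle genes (Cdkn1a, 1.66-fold; profile 0.889) and 14 endothelial genes (Robo4, 1.49-fold; profile 0.607).

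No member passed by either count among autonomic receptors (28 measured), urothelium (26), fibroblast and matrix (24), heat shock (19), immediate early (19) and sterol synthesis (20) genes. The same held for lists of tissue that could accompany a bladder sample, which were adipocyte (17), skeletal muscle (15), red blood cell (5), leukocyte (22), nerve and Schwann cell (14) and female reproductive tract (11) genes. Their mean profiles had adjusted exact p-values of 0.301 for heat shock, 0.607 for urothelium, adipocyte, skeletal muscle, leukocyte, nerve and reproductive tract, 0.682 for red blood cell and 0.889 for the rest. The hepatocyte list, added later, differed between arrays of 1 time: its mean was -1.12 SD units in CT20 replicate 1 and 1.57 in CT20 replicate 2. Slow and cardiac muscle genes averaged -0.65 at CT20 and 0.28 at CT0, and autonomic ganglion genes -0.91 at CT20 and 0.67 at CT4 (exact permutation p = 0.161 and 0.309 for their 24 h waves, 0.801 for hepatocyte).

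**Figure D4:**
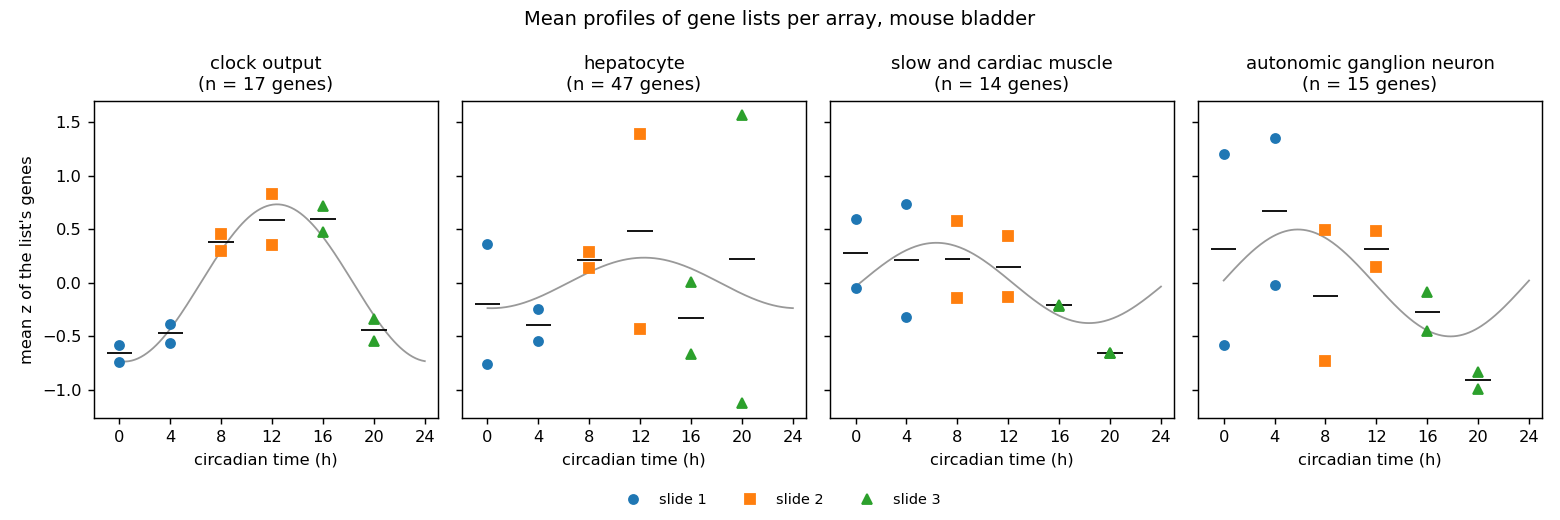
Mean z of the measured genes of 4 lists (clock output 17, hepatocyte 47, slow and cardiac muscle 14, autonomic ganglion neuron 15) against circadian time in hours. Points are single arrays by slide, bars means of 2 arrays and curves fitted 24 h waves; replicates lie close together for the clock output list and up to 2.69 apart for the hepatocyte list.

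A test for any difference between the 6 times, with no shape assumed, took 17 genes past the threshold, and 3490 had an unadjusted p under 0.05. Nr1d1 (adjusted p = 0.00348), Ciart and Tef (both 0.00552) and Arntl (0.0177) were among the 15 that also had a 24 h wave. The other 2, chosen after their values were seen, were the olfactory receptor gene Olfr1032 (adjusted p = 0.0452) and an unnamed transcript with the probe name NAP029330-1 (0.0419), both far below the 75th percentile. With the slide block, which leaves the differences between the 2 times of each slide, limma took 0 genes past the threshold (2820 unadjusted), and with slide as a random block 7. Without the 3 arrays highest in hepatocyte transcripts it was 0 (2415 unadjusted) and without the 3 highest in slow muscle transcripts 0 (3859 unadjusted). The count was 137 without CT0 replicate 1, 9 without either array of CT4, 10 without CT8 replicate 2, 7 without CT12 replicate 2, 9 without CT16 replicate 2 and 8 without either array of CT20. Tested 1 slide at a time, Nr1d2 fell by 1.19 ± 0.10 (log2, SE) from CT16 to CT20 (limma adjusted p = 0.0414); it was the 1 gene past the threshold, with 0 from CT0 to CT4 (1706 unadjusted) and 0 from CT8 to CT12 (2368 unadjusted).

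No gene had a 12 h component past the threshold in limma beyond its 24 h wave; 1959 had an unadjusted p under 0.05. Per1 had a 12 h amplitude of 0.52 ± 0.08 (log2, limma adjusted p = 0.255), Arntl one of 0.35 ± 0.11 (adjusted p = 0.435) and Nr1d1 one of 0.15 ± 0.07 (adjusted p = 0.586). Without CT4 replicate 1, 1 gene passed, Kndc1, which lies near background. On simulated data the same fit recovered 170 of 200 waves of 12 h with amplitude 1. Smaller 12 h waves were not simulated, so this recovery does not bear on them. All 200 waves were simulated at once. The Benjamini-Hochberg adjustment is stricter where few genes have a wave, so the recovery does not hold for few such genes.

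The comparison of CT12 with CT0 contrasts the start of the subjective night with the start of the subjective day. Ciart was higher at CT12 by 4.11 ± 0.33 (log2, SE, 2 arrays against 2, limma adjusted p = 0.00847), Dbp by 3.14 ± 0.28 and Usp2 by 2.38 ± 0.28. Arntl fell by 2.71 ± 0.25 (limma adjusted p = 0.0122), Spon2 fell by 2.53 ± 0.29 and Adamts4 fell by 2.39 ± 0.33. In all, 36 genes passed, 24 higher and 12 lower at CT12, and 30 of them had a 24 h wave past the threshold. That balance is not stable, being 74 higher and 103 lower without CT0 replicate 1 and 6 of each without the 3 arrays highest in slow muscle transcripts. Gja1 was higher by 0.69 ± 0.18 (limma adjusted p = 0.276). The arrays compared lie on different slides, so time and slide cannot be told apart in this contrast; 8 genes passed with slide as a random block, 16 with the hepatocyte profile as a covariate, 0 in limma without the 3 arrays highest in hepatocyte transcripts (1233 unadjusted) and 12 without the 3 highest in slow muscle transcripts. The count was 177 without CT0 replicate 1, 13 without CT0 replicate 2, 12 without any 1 array of CT4 or CT8, 4 without CT12 replicate 2, 13 without either array of CT16 and 11 without either of CT20.

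Nr1d1 and Per2 moved in opposite directions between CT4 and CT16. Nr1d1 fell by 2.72 ± 0.16 (log2, SE, 2 arrays against 2, limma adjusted p = 0.00397), and Per2 was higher by 1.68 ± 0.24 (adjusted p = 0.0413). Angptl7 was higher by 2.55 ± 0.31 and Cys1 by 2.16 ± 0.17, while Spon2 fell by 2.11 ± 0.29 and Creg2 fell by 1.84 ± 0.24. In all 73 genes passed, 41 higher and 32 lower at CT16, with 22 of them among the 24 h genes. In some other settings the count was larger, among them 340 with the authors' table, 453 with normexp and 952 with array weights. The balance turned to 6 higher and 14 lower with no filter on dim probes, 38 and 39 without either array of CT0, 11 and 12 with the hepatocyte covariate and 2 and 3 without the 3 arrays highest in hepatocyte transcripts; it was 17 of each without either array of CT12. Gja1 was higher by 0.52 ± 0.18 (limma adjusted p = 0.158). Slide and time cannot be told apart here either: 2 genes passed with slide as a random block, 23 with the hepatocyte covariate, 5 without the 3 arrays highest in hepatocyte transcripts and 0 in limma without the 3 highest in slow muscle transcripts (3012 unadjusted). The count was 0 without CT4 replicate 1 (2510 unadjusted) or CT4 replicate 2 (3071 unadjusted), 5 without CT16 replicate 1, 2 without CT16 replicate 2, 34 without either array of CT12 and 6 without either of CT20.

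From CT8, in the subjective day, to CT20, late in the subjective night, Dbp and Nr1d1 fell and Arntl rose. Ciart fell by 5.66 ± 0.33 from CT8 to CT20 (log2, SE, 2 arrays against 2, limma adjusted p = 0.00128), Dbp fell by 4.03 ± 0.28 and Nr1d1 fell by 3.25 ± 0.16 (adjusted p = 0.00103). Arntl was higher at CT20 by 2.73 ± 0.25 (limma adjusted p = 0.0129), Nfil3 by 1.56 ± 0.13 and the endothelial proteoglycan gene Esm1 by 1.44 ± 0.16 (adjusted p = 0.0443). In all 11 genes passed, 4 higher and 7 lower at CT20, and 10 of them were 24 h genes. Without CT20 replicate 2 the balance turned to 7 higher and 6 lower. Gja1 fell by 1.02 ± 0.18 (limma adjusted p = 0.133). These arrays too lie on different slides, and 7 genes passed with slide as a random block, 2 without the 3 arrays highest in hepatocyte transcripts and 0 in limma without the 3 highest in slow muscle transcripts (2914 unadjusted). The count was 7 without either array of CT4, 7 without CT8 replicate 2 and 7 without CT20 replicate 1.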

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

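The random slide block, the slide-centred list test, the hepatocyte covariate and the fits without 3 arrays were chosen after the data had been seen; the other settings were planned. The 24 h count of 114 moved to 60 with an F-test without the variance prior, 62 with median scaling, 50 with no filter on dim probes, 222 over every probe, 201 with array weights, 2 with the slide block, 28 with slide as a random block, and 18 without the 3 arrays highest in hepatocyte or in slow muscle transcripts; without 1 array it was 42 to 104. The any-time count of 17 became 48 with normexp, 46 with the authors' table, 36 with genes above background on all 12 arrays, 32 with array weights, 47 with an intensity trend, 0 with the slide block (limma, 2820 unadjusted) and 7 with the random block, and 7 to 137 without 1 array. The 12 h count stayed at 0 (limma, 1422 to 2833 unadjusted) except for 1 without CT4 replicate 1, a range of 0 to 1. CT12 against CT0 (36) became 13 with no filter, 15 with array weights, 8 with the random block and 16 with the hepatocyte covariate, and 4 to 177 without 1 array. CT16 against CT4 (73) became 453 with normexp, 340 with the authors' table, 221 with genes above background on all arrays, 354 over every probe, 952 with array weights, 402 with a trend, 42 with median scaling, 20 with no filter, 2 with the random block and 23 with the covariate, and 0 to 77 without 1 array. CT20 against CT8 (11) became 7 with the replicate block, 7 with array weights, 18 with a trend and 7 with the random block, and 7 to 13 without 1 array. Without the 3 arrays highest in hepatocyte transcripts the any-time count was 0 (2415 unadjusted), CT12 against CT0 gave 0 (1233), CT16 against CT4 gave 5 and CT20 against CT8 gave 2; without the 3 highest in slow muscle transcripts they were 0 (3859), 12, 0 (3012) and 0 (2914). Of the lists, 1 passed; 4 passed with members not divided by their SD (core clock, clock output, glucocorticoid-responsive, Rev-erb and Sp1) and 0 with slide means removed, where the clock output list had an exact p of 0.0278 and 3 other lists the smallest, 0.00926; without 1 array it stayed 1. Fewer arrays leave fewer degrees of freedom and the slide block removes the differences between slides; for the other settings, and for the rises without CT0 replicate 1, the cause was not tested. With the hepatocyte covariate over all 12 arrays the 24 h count was 86, the any-time count 15 and CT20 against CT8 gave 10. The core clock count of 9 became 6 with the replicate block and 6 with the hepatocyte covariate. Arrays share only a replicate number across times. Deviations from the time mean correlated over 0.1 in 20 of 30 pairs with the same number (from -0.20 to 0.44). Of the 12 arrays, 10 correlated best with their own number, a hint from the data and not the design. With 2 arrays per time the 2 deviations are mirror images, so both counts hold each distinct value 2 times and overstate the evidence. No named gene reversed direction in any setting run. The balance of higher and lower genes did turn: for CT12 against CT0 (24 and 12) to 74 and 103 without CT0 replicate 1, for CT16 against CT4 (41 and 32) to 6 and 14 with no filter, 38 and 39 without either array of CT0, 11 and 12 with the covariate and 2 and 3 without the 3 arrays highest in hepatocyte transcripts, and for CT20 against CT8 (4 and 7) to 7 and 6 without CT20 replicate 2. The share of 24 h genes with a night peak moved from 35.1% to 51.6% with median scaling and to 0% of the 2 genes left with the slide block. Over settings other than left-out arrays, the 24 h call of a named gene was kept or still absent 625 times, lost 100 times and gained 7 times, and contrast calls were kept 185 times and lost 67 times. With 1 array left out, 24 h calls were unchanged 485 times and lost 103 times, and contrast calls were unchanged 127 times and lost 89 times. The contrasts and the 12 h terms could not be fitted with slide as a fixed block, a scan-date block had only 1 day, and a time left with 1 array was assumed to vary like the others. Npas2 and Per3, with mean levels of -5.20 and -5.17 (log2), were well above background on 10 and 11 arrays, so the filter on all 12 gave them no value.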

Other observations

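Several genes outside the fixed lists and the naming rule had 24 h waves past the threshold; they were picked after their values were seen. Gucy1a1, encoding a subunit of the nitric oxide receptor guanylate cyclase, peaked at CT4.4 (2.23-fold, limma adjusted p = 0.0461), and Dag1, the dystroglycan gene, at CT4.0 (1.53-fold, adjusted p = 0.0461). Il15 peaked at CT12.3 (1.87-fold, adjusted p = 0.0315), the interferon-induced gene Ifit3 at CT13.1 (1.69-fold, adjusted p = 0.00402), the macrophage receptor gene Cd163 at CT10.5 (2.02-fold, adjusted p = 0.0461) and the chemokine gene Cxcl12 at CT10.8 (1.54-fold, adjusted p = 0.0481). The antimicrobial peptide gene Defb1 peaked at CT22.0 (1.77-fold, adjusted p = 0.0498). Col5a3, a collagen gene, peaked at CT4.7 (3.18-fold, adjusted p = 0.0208). The elastic fibre genes Eln (4.46-fold, CT1.3, adjusted p = 0.123), Fbn1 (2.37-fold, CT3.8, 0.156) and Loxl1 (1.80-fold, CT2.9, 0.189) missed the threshold. In the endoplasmic reticulum folding list 10 of 19 genes had an unadjusted p under 0.05, among them Hspa5 (1.45-fold, CT22.5), Creld2 (1.43-fold) and Hyou1 (1.41-fold, CT19.7), while the list's mean profile had an exact p of 0.0723 (adjusted p = 0.301).

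The test that counted 24 h genes outside the clock lists under within-slide assignments and both tests of the hepatocyte genes were chosen only after the results were seen; the description and the reading of the slope test outside the clock lists were narrowed afterwards, its value being unchanged. A chance assignment of arrays to times is argued against for the 24 h count. Of 100 assignments of the 12 arrays to times, 1, the real one, gave 114 genes, and the highest other gave 47. The same held for the any-time count, where 1 of 100, the real one, gave 17 and the highest other 4. A share of 1 in 100 is the smallest this test can give. These assignments did not keep the slide layout, so neither count bears on differences between slides.

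The 24 h wave of the clock genes was set against a difference between slides as its cause. For the 35 genes of the 2 clock lists, the differences between the 2 times of a slide followed those that the 3 slide means predict for a 24 h wave, with a slope of 0.847 (exact one-sided permutation p = 0.00463, the smallest of 216 assignments; highest other 0.780), which slides alone would not give. Outside these lists 64 genes passed the 24 h threshold when the lists were left out of the fit; 1 of 100 within-slide assignments, the real one, gave as many and the highest other gave 40, so slides alone are also argued against for that count. For the 95 genes outside the lists that differed most between slides, 17 of them 24 h genes, the slope was 0.136 (exact one-sided p = 0.0694, highest other 0.239). This decides nothing for or against slide differences, since 78 of these genes had no 24 h wave past the threshold and genes picked by their slide means have their slope pulled toward 0. Circadian time, the study's own variable, remains a hypothesis for the clock genes, and which single genes outside the lists owe their wave to slide cannot be read from these arrays.

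Transcripts typical of hepatocytes varied by large amounts between arrays of 1 time. Replicate 2 had the higher mean at each time but CT8, and the labels do not say what the number marks. Alb ranged from -2.19 to 4.12 and Ahsg from -2.73 to 3.83 (log2) over the 12 arrays; of the 47 measured genes, 34 were well above background on every array and 1 is also on another list. A time-of-day change is argued against as the whole cause, since the largest gap between 2 arrays of a time, 2.69 SD units, exceeded the range of the 6 time means, 0.873 (exact permutation p = 0.801 for a 24 h wave). RNA of hepatocytes in some samples may be the source: 89.4% of the genes (42 of 47) were higher by over 1 in CT20 replicate 2 than in replicate 1, with a median difference of 5.10. The list and these arrays were chosen after this difference had been seen, so the values do not support that source beyond the difference itself. The share also lies just under the 90% set for this explanation, and the 5 others were Rbp4, Trf, Fbp1 and Ass1, with a high level on all arrays, and Ttr, so hepatocyte RNA cannot be told apart from a change within bladder tissue, nor from something shared by arrays of 1 replicate number; no biological explanation other than time was tested.

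The 12.0-fold wave of Tcap was set against the amount of striated muscle in the samples. With the skeletal muscle profile as a covariate 93.9% of its amplitude was left (60.1% after subtracting 2 SE), which argues against muscle content as the whole cause. The fold went from 12.0 to 10.3 and the SE of the amplitude from 0.286 to 0.303 (log2), and the call ended (limma adjusted p from 0.0458 to 0.109) as the amplitude fell slightly and its SE rose. Over the 15 skeletal muscle genes the median amplitude along the wave of Tcap was 0.27 and the highest 0.62, against 1.79 for Tcap. A clock-driven Tcap rhythm is a hypothesis that stays open, resting on 2 arrays per time.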
